A study of Mus musculus with 2 samples.

How the data were processed

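Flash-frozen hippocampus of adult mice was processed for droplet-based single-nucleus ATAC-seq, per the labels, with 1 wild-type and 1 Htr6-knockout library. The submitters' processing notes name Cell Ranger ATAC 1.2.0, Seurat 4.0.4, Signac 1.3.0, R 4.1.1 and the mm10 build, without the role of each. How fragments were filtered, peaks called, nuclei clustered, values normalised and genotypes tested, and how doublets were treated, is not given in the sources used here.

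There were 8 deposited tables, all of the whole series: marker peaks and marker gene activities of 19 numbered and of 11 merged clusters, the peaks and gene activities that differed between genotypes in CA1 nuclei, and the lower and higher CA1 peaks as intervals. Per the file headers, each row of the marker and genotype tables gives a p-value and an adjusted p-value, both by the authors. The lists of intervals have no header and hold coordinates only. The adjusted p-value was the p-value times 156573 in the CA1 peak table and 21807 in the CA1 gene activity table. Nuclei of 1 library are not replicates, so none of the authors' deposited p-values is printed. They were used only in alternative filters, of CA1 peaks and of strict marker peaks. The average log2 fold change is the authors' deposited value on a normalised scale that the headers do not define. The deposited fraction of nuclei in which a peak or gene had signal is given per the file headers for each side of a comparison and is printed here as a percent. In the CA1 tables the first side was taken as knockout and the second as wild type, because negative log2 fold changes matched the deposited lower list and positive ones the higher list for all peaks analysed here. The smallest absolute log2 fold change in the CA1 peak table was 0.25, and each peak had at least 10% of nuclei of 1 genotype, so weaker or rarer peaks were not seen. A further 2 peaks of the lower list had no values here and were not analysed here. Coordinates are as deposited, and whether they count from 0 or 1 is not stated. Sequencing depth and numbers of nuclei are unknown, so no interval is given for any share.

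Peaks were assigned to the gene and region in the authors' annotation: coding exon, UTR, intron or other exon at a distance of 0 bp, and otherwise outside genes. A gene assigned to a peak outside genes is the closest one, which need not be regulated by it. A RefSeq gene table of the same build (GRCm38.p6) gave the position of Htr6 and an alternative definition of peaks outside genes, and 94.1% of the CA1 peaks carried a gene name found in it.

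The following choices were made before the data were examined. There were 15 gene lists and 13 classes of cell type markers. The text names every Htr6 peak, the 12 lowest and 12 highest CA1 peaks by log2 fold change, the 5 genes with the most lower and the 5 with the most higher peaks, every gene of the CA1 gene activity table, up to 3 members with the lowest and 3 with the highest log2 fold change per list, and the 3 leading genes and the fixed markers of merged clusters. Ties went to the larger difference in share. Where a list or class is long, only some of the members so chosen are printed. A gene list and some genes that this rule names are not reported here.

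For each list with at least 5 listed peaks, the median log2 fold change was placed among those of 10000 random lists with the same number of peaks in each of 10 bins of mean share, drawn from the listed CA1 peaks. Numbers of higher peaks per region, chromosome or marker set were placed in the same way. Lists below percentile 2.5 or above 97.5 were counted as standing apart. Such a percentile describes these libraries and is not a test between genotypes. Marker peaks were matched to CA1 peaks by at least 1 bp of overlap. Numbered and merged clusters were compared by the Jaccard index of their marker peaks with direction. The share of wild-type nuclei among CA1 nuclei was estimated by least squares as the weight that makes the merged cluster's shares from the 2 genotypes' shares.

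The procedures were tested on simulated data. With 40 lists of 30 peaks drawn from the 4449 CA1 peaks, 0% stood apart with no shift, 87.5% with a shift of -0.25 and 95% with a shift of 0.25 (log2). These percents hold for simulated lists of 30 peaks and do not carry over to shorter lists. For the 5 primary cilium peaks, the central range of random medians was -0.49 to 0.29. The deposited log2 fold changes have no value between -0.25 and 0.25, and some listed peaks share a gene. Whether the percents hold for such values was not tested. Alternatives covered stricter filters, merging of neighbouring peaks, other matching of random lists and other definitions of overlap. Motif and GC analyses and promoter windows needed a genome sequence and gene strands and were not run. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.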

Results

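Chromatin accessibility was measured by single-nucleus ATAC-seq, in which a transposase cuts and tags open DNA inside droplet-barcoded nuclei, in flash-frozen whole hippocampus of adult mice. There were 2 libraries, 1 from a wild-type hippocampus and 1 from an Htr6-knockout hippocampus. Htr6 encodes serotonin receptor 6, a Gs-coupled receptor found on neuronal primary cilia. With 1 library per genotype no difference below has a replicate check, and no p-value, error or interval is given for it. The tables hold shares of nuclei and fold changes, not counts, so the depth of each library and the number of nuclei behind each share are unknown.

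The authors grouped the nuclei into 19 numbered clusters and 11 merged, named clusters, and compared the genotypes within the merged CA1 cluster, the pyramidal neurons of hippocampal field CA1. The named clusters are described first, then the knockout comparison in CA1.

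Microglia, oligodendrocytes and astrocytes carried the full marker sets fixed for them. Gene activity, which sums the ATAC signal over a gene, was listed as higher for 12 of 12 microglial markers in the microglia, 12 of 12 oligodendrocyte markers in the oligodendrocytes and 11 of 11 astrocyte markers in the astrocytes. In the authors' deposited table, Inpp5d, a lipid phosphatase of blood-lineage cells, had signal in 84.9% of microglia and 23.7% of other nuclei, with a log2 fold change of 1.48. Mbp, a major myelin protein, reached 92.1% of oligodendrocytes against 56% of other nuclei (log2 fold change 1.44 in the authors' deposited table), and Slc1a2, the main astrocytic glutamate transporter, 88.7% of astrocytes against 41.9%. Oligodendrocyte precursors (OPC) had 6 of 8 precursor markers listed as higher, among them Pdgfra and Cspg4; Cspg4 had signal in 70.3% of OPC and 20.7% of other nuclei in the authors' deposited table.

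Dentate granule cells (DGC) had 8 of 10 granule cell markers listed as higher, including Prox1, the transcription factor of granule cell identity, and their leading genes were Glis3, Sema5a and Stxbp6. CA1 neurons had 4 of 8 CA1 markers, among them Mpped1, Man1a and Fibcd1, and CA3 neurons had 4 of 9 CA3 markers (Grik4, Cpne4, Hs3st4 and Trps1). The leading CA1 genes included Khdrbs3, with signal in 77.7% of CA1 nuclei and 48.5% of other nuclei and a log2 fold change of 0.73 in the authors' deposited table, and Prkcb, a protein kinase C. In CA3 the leading genes were Khdrbs3, Grik4 and Spock1, with Grik4, a kainate receptor subunit, in 90.2% of CA3 nuclei and 70.7% of other nuclei in the authors' deposited table. The cluster named interneuron_1 had 5 of 16 GABAergic markers listed as higher: Gad1 and Gad2, which make GABA, the transcription factors Dlx1 and Lhx6, and Nxph1. In the authors' deposited table Gad2 had signal in 30.9% of interneuron_1 nuclei and 6.4% of other nuclei. The cluster named interneuron_2 had only Gad1 of those 16 listed as higher. Tshz2 led excitatory_1 and Hs3st4 led excitatory_2, with log2 fold changes of 1.21 and 1.09 in the authors' deposited table.

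The marker tables of the merged clusters held 32035 peak entries, 23253 higher and 8782 lower in their cluster. Each of the 23253 higher entries was open in a larger share of the cluster's nuclei than of the others, and 33 of the 8782 lower entries, 32 of them in DGC, were too. Of the 19 numbered clusters, 4 had marker peak sets identical to those of a merged cluster (interneuron_1, interneuron_2, excitatory_2 and OPC). Another 14 fell into 7 pairs that shared their closest merged cluster: DGC, CA1, CA3, excitatory_1, astrocytes, oligodendrocytes and microglia. In each pair, 1 member had a smaller share of nuclei open at the marker peaks that were higher in both. The median ratio of the smaller to the larger share was 0.272 in CA3, 0.305 in CA1, 0.317 in astrocytes, 0.343 in oligodendrocytes, 0.347 in excitatory_1, 0.367 in microglia and 0.371 in DGC. Numbered cluster 13 was closest to excitatory_2, but with an overlap of only 0.0847 (Jaccard index, shared peaks over all peaks of both sets).

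The knockout comparison in CA1 asked where open chromatin differed between the genotypes in these neurons. The targeted gene came first: Htr6 (mm10 chromosome 4, 139059706 to 139075570 in the RefSeq gene table) had 0 listed CA1 peaks and no entry in the CA1 gene activity table. Peaks absent from these tables did not pass the authors' filters and were not analysed here, so the tables do not show whether the receptor gene was disrupted. A single Htr6 peak was listed in any cluster, in numbered cluster 2 of the dentate granule pair (chromosome 4, 139067601 to 139068903). It was open in 15.4% of that cluster's nuclei and 3.2% of other nuclei in the authors' deposited table.

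The authors listed 3340 CA1 peaks as lower and 1111 as higher in the knockout, and 3338 and 1111 of these were analysed here. The direction of each list was that of the authors' log2 fold change. The shares of open nuclei went another way. All 4449 peaks, including each of the 1111 listed as higher, were open in a smaller share of knockout than of wild-type nuclei in the authors' deposited table. The median ratio of knockout to wild-type share was 0.202 for the lower peaks and 0.373 for the higher peaks. The lower peaks had a median of 2.6% of knockout and 13% of wild-type nuclei, and the higher peaks 5.1% and 13.6%, in the authors' deposited table. On the authors' fold scale the higher list thus held peaks with a lesser shortfall in share, not peaks open in more nuclei. All 4449 peaks were open in at least 10% of wild-type nuclei, and 81 reached that share in the knockout.

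**Figure D1:**
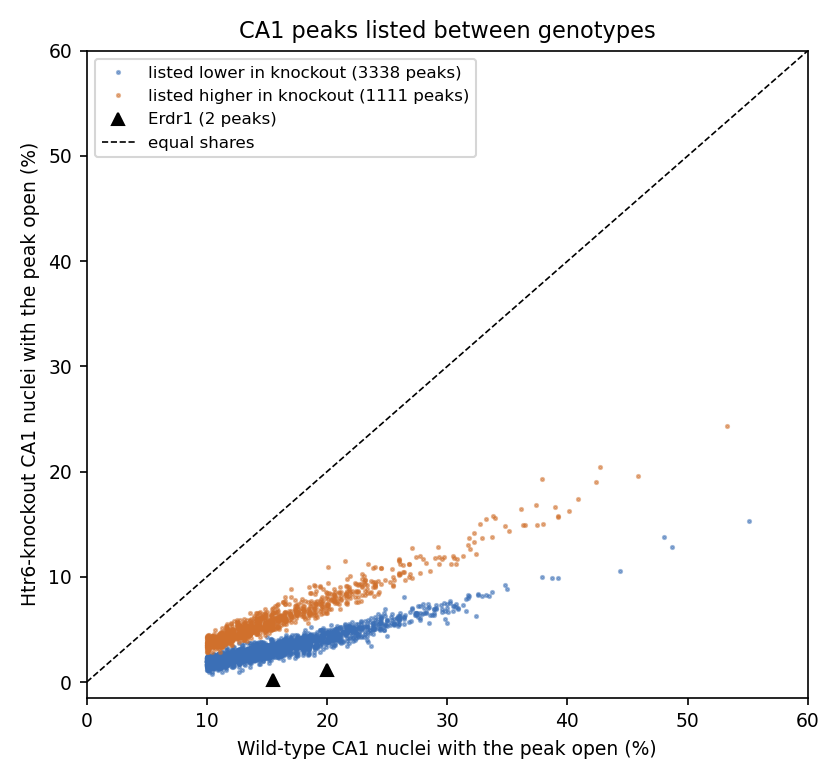
Share of CA1 nuclei in which each of 4449 listed peaks was open, wild type on the x axis and Htr6 knockout on the y axis, both in percent; each point is 1 peak, coloured by the authors' list, triangles mark the Erdr1 peaks and the dashed line marks equal shares. All points lie below the line, and the peaks listed as higher (median ratio 0.373) lie above those listed as lower (median ratio 0.202).

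The lowest peaks were both at Erdr1, a gene near the end of chromosome Y. The first (chromosome Y, 90797540 to 90801006, intron; gene ENSMUSG00000096768) was open in 0.2% of knockout and 15.5% of wild-type nuclei, a log2 fold change of -2.06 in the authors' deposited table. The second (chromosome Y, 90806594 to 90809609, intron) was open in 1.1% and 20%, with -1.57 in the authors' deposited table. The other 10 of the 12 lowest peaks had log2 fold changes no higher than the -1.13 at Zmynd8 in the authors' deposited table, with Gm11680 the lowest of them. They included introns of Lhfp (-1.45 in the authors' deposited table) and Uggt2, a glycoprotein glucosyltransferase of the endoplasmic reticulum (-1.36), and peaks outside genes nearest to Kif21a, a kinesin motor (-1.34), and Kit, the stem cell factor receptor (-1.16). The remaining peaks were nearest to or within Gm28543, Gm11846, RP24-559D1.1 and Gm4894.

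The 12 highest peaks ranged from 0.57 at Dnajb5 to 0.52 at Abca7 in the authors' deposited table. The Dnajb5 peak (chromosome 4, 42956915 to 42960565, coding exon; gene ENSMUSG00000036052), at a heat shock protein 40 family gene, was open in 7.4% of knockout and 16.5% of wild-type nuclei in the authors' deposited table. A UTR peak of Kcnd3, a potassium channel of the A-type current, had 6% against 13.1% and a log2 fold change of 0.56 in the authors' deposited table. The others were within Eif2d, Fuca1, Gm14340, Arhgef28, Magoh, Fam192a and Abca7, a lipid transporter, or outside genes and nearest to 4930544M13Rik, C2cd4d and Prkd1, the last at a distance of 394100 bp.

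Genes with several lower peaks included Atp2b1, a plasma membrane calcium pump, with 9 lower peaks and 2 higher; Cdh11, a cadherin, with 8; Celf2, an RNA-binding protein, with 7 and 1 higher; Dab1, the reelin adaptor, with 7; and Prkca, a protein kinase C, with 6. The lowest of these was a Celf2 intron peak at -0.88 in the authors' deposited table. Lincpint, a long non-coding RNA, had the most higher peaks (4, all in introns), and Tcf4, Dscaml1, Sbk1 and Srcin1 had 3 each, with 1 lower peak each at Tcf4 and Dscaml1. A Lincpint peak at 0.51 and a Dscaml1 peak at 0.38 were the highest of these in the authors' deposited table.

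Summed over whole genes, 3 genes differed in the CA1 gene activity table. Erdr1 had signal in 2.2% of knockout and 40.8% of wild-type nuclei, with a log2 fold change of -0.31 in the authors' deposited table. Zeb2, a zinc finger transcription factor, had 58.8% against 91.2% and -0.26 in the authors' deposited table, and 2 Zeb2 peaks were on the lower list. Hmcn1, an extracellular matrix protein, was listed as higher at 0.26 with 35.6% of knockout and 62.3% of wild-type nuclei in the authors' deposited table, so its share too was smaller in the knockout.

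The 2 lists lay in different parts of genes. Of the higher peaks, 54.2% were in coding exons and 13.1% in UTRs, against 15.5% and 4.73% of the lower peaks. Of the lower peaks, 41.7% were outside genes and 37.9% in introns, against 13.2% and 19.1% of the higher peaks. Among 10000 random draws of listed peaks matched on mean share, the number of higher peaks in coding exons lay at percentile 100 and the number outside genes at percentile 0, as a description of these libraries. The higher peaks were also wider, with a median of 2257 bp against 973 bp. Of the 890 narrowest peaks 5.96% were listed as higher, and of the 889 widest 62.1%.

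**Figure D2:**
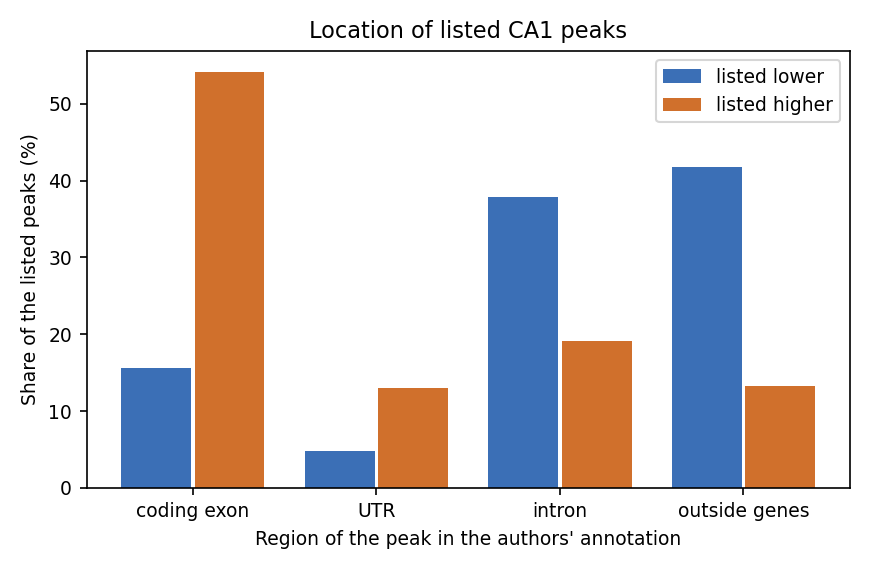
Share of the peaks listed lower and higher in knockout CA1 nuclei (y axis, percent of each list) by the region they fall in (x axis), from the authors' annotation; other exons, with 9 peaks, are not drawn. Coding exons hold 54.2% of the higher and 15.5% of the lower peaks.

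Chromosomes differed as well. On chromosome 17 the lists held 65 higher and 65 lower peaks, on chromosome 7 they held 110 and 116, and on chromosome 19 they held 45 and 50. Higher peaks made up 25% of all listed peaks, 14.8% of those on chromosome 6 and 11.9% of those on chromosome X. The numbers of higher peaks on chromosomes 7 and 17 lay at percentile 100 of draws matched on share and also on width, as a description of these libraries. These draws were not matched on region. Whether the chromosomes differ beyond the regions of their peaks was not tested.

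Lower CA1 peaks included the neurons' own markers. Of 8 CA1 marker genes, 7 had listed peaks, 13 in all and each of them lower: Wfs1 had the lowest, open in 1.6% of knockout and 11.8% of wild-type nuclei in the authors' deposited table, the Fibcd1 peak was at -0.58 and the Mpped1 peak was at -0.25. Of 9 markers of excitatory neurons, 3 had peaks, among them Bcl11b and Neurod6, 6 in all and each lower. Markers of other cell types were sparse. Oligodendrocyte, precursor and Cajal-Retzius markers had 0 listed peaks; astrocytes had 1 lower peak at Gjb6; microglia had 2 lower peaks at Inpp5d and 1 higher at Cx3cr1; GABAergic markers had 2 lower and 1 higher. Endothelial and mural markers had 4 lower peaks, CA3 and granule cell markers 3 each, and subicular and fibroblast or choroid plexus markers 2 each.

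The marker peaks of the merged clusters gave a related picture, but they come from the same 2 libraries, and those of CA1 from the same nuclei. They are thus not independent of the genotype comparison. Of 266 listed peaks that were lower in the CA1 cluster than in other cells, 228 were listed as higher in the knockout, and of 179 peaks higher in CA1, 33 were. This was not particular to CA1: of the listed peaks lower in CA3 neurons 70 of 77 were on the higher list, and of those lower in granule cells 113 of 130. Of 408 listed peaks that marked oligodendrocytes, 321 were on the higher list, as were 180 of 261 for microglia and 102 of 156 for astrocytes. For peaks higher in their cluster the numbers were 87 of 271 for granule cells, 18 of 68 for CA3 neurons and 15 of 40 for OPC. Matched on both share and width, oligodendrocytes and microglia lay at percentile 100 and astrocytes at 99.99, OPC at 0.905 and granule cells at 0, as a description of these libraries. With strict markers, of log2 fold change at least 1, the first 3 no longer stood apart: 30 of 57 oligodendrocyte peaks (percentile 75.2), 47 of 99 microglia peaks (62.1) and 22 of 49 astrocyte peaks (37.1) were on the higher list.

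Gene lists chosen for the receptor and the tissue were compared next; of 15 lists, 14 had at least 5 listed peaks. Axon guidance and cell adhesion genes were the most one-sided, with 65 lower and 2 higher peaks over 34 of 50 genes. The lowest were at Epha3, an ephrin receptor (-0.82), Ntm (-0.79) and Dscam (-0.75), and the higher ones at Opcml (0.27) and Ncam2 (0.26), in the authors' deposited table. The list's median log2 fold change of -0.42 lay at percentile 0.115 of 10000 random lists matched on share, as a description of these libraries. With width matched too, it lay at 0.865. The random lists were not matched on region. Of all listed peaks, 14.4% of those in introns were on the higher list, against 53.7% of those in coding exons. Whether this list stands apart beyond the regions of its peaks was not tested. Chromatin and histone acetylation genes were split almost evenly, with 10 higher and 9 lower peaks over 12 of 40 genes. Their median was 0.26, at percentile 99.7. No listed peak lies between -0.25 and 0.25, so the sign of this median turns on 1 peak. The median difference in share, knockout minus wild type, was -8.9 percentage points. Dnmt3a, a DNA methyltransferase, had peaks at 0.39 and 0.34 and Hdac4 at 0.38, while Hdac5 had -0.61 and Tet2 -0.46, in the authors' deposited table. Matched also on width, this list lay at percentile 84.8, within the range of random lists.

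The signalling lists given here lay within the range of random lists. Genes of cAMP and PKA signalling, the pathway downstream of a Gs-coupled receptor, had 24 lower and 2 higher peaks over 16 of 32 genes, with a median at percentile 8.59. Pde10a had -0.63 and Akap6 -0.56, and Pde2a was higher at 0.41, in the authors' deposited table. With only peaks within 50 kb of the gene, this list lay at percentile 0.94, outside the range. Gq, phospholipase C and calcium genes had 44 lower and 3 higher peaks (percentile 13.8), with Dgki at -0.80 and Orai2 at 0.31 in the authors' deposited table. Primary cilium genes had only 5 peaks in 40 genes, 3 lower (Ift80, Gpr161 and Ahi1) and 2 higher (Ift172 and Kif17), at percentile 46.2. Serotonin genes had 4 lower peaks, at Htr5b, Htr1f, Htr1b and Htr4, and 1 higher at Slc18a2, the vesicular monoamine transporter (percentile 59.2).

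Synaptic and channel genes behaved like the listed peaks in general. Glutamate receptor and postsynaptic density genes had 51 lower and 9 higher peaks (percentile 18.7), with Dlgap1 at -1.04 and Gria2, an AMPA receptor subunit, at 0.38 in the authors' deposited table. Inhibitory postsynaptic genes had 12 lower and 2 higher (percentile 36.1), presynaptic release genes 19 and 4 (percentile 30.6), potassium channels 30 and 3 (percentile 16.7), and calcium and sodium channels 18 and 5 (percentile 49.3). Syn1 had -0.82, Kcnt2 -1.09 and Cacnb2 -0.75 in the authors' deposited table. Activity-regulated genes had 7 lower peaks and 1 higher (percentile 62.8). The higher one was at Arc, an immediate early gene, open in 19.6% of knockout and 45.9% of wild-type nuclei with a log2 fold change of 0.33 in the authors' deposited table, and the lowest was at Homer1 (-0.84). The comparison lists had few peaks: oxidative phosphorylation 3 lower and 2 higher (percentile 68.7), and cytosolic ribosome 1 and 1, too few for a percentile.

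**Figure D3:**
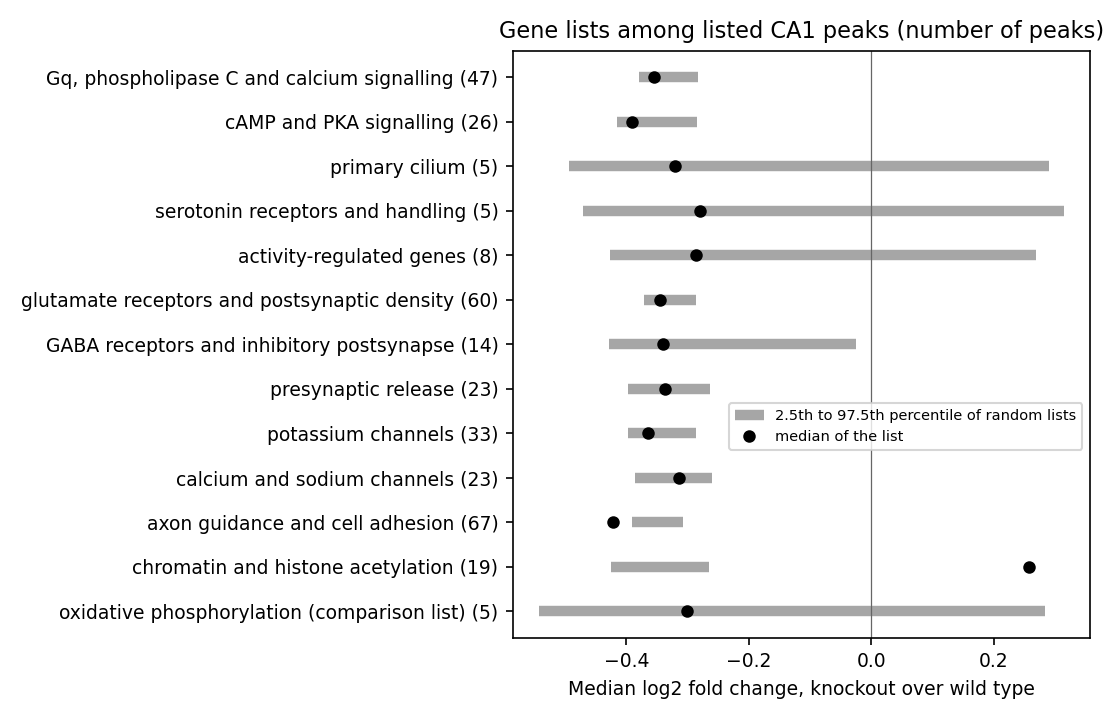
Median log2 fold change, knockout over wild type, of the listed CA1 peaks of each gene list reported here (points, x axis), with the number of peaks in brackets and the central range of 10000 random lists matched on share (grey bars). Axon guidance and cell adhesion (-0.42) and chromatin and histone acetylation (0.26) lie outside their bars; the chromatin list does not when width is also matched.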

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

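The direction of peaks by the sign of the difference in share or by the log2 ratio of shares, a share of at least 5% in both genotypes, the RefSeq table and matching on peak width were chosen after seeing the data; the others, the gene lists by median difference in share among them, were planned. By the sign of the difference in share, 0 peaks were higher. By the log2 ratio of shares the median of the higher peaks was -1.42 and that of the lower peaks -2.31, so the direction of the higher list reversed. The same held for the 12 highest peaks: Dnajb5 -1.16, Eif2d -1.13, Kcnd3 -1.13, Fuca1 -1.27, Gm14340 -1.42, 4930544M13Rik -1.29, Arhgef28 -1.17, Magoh -1.34, C2cd4d -1.49, Prkd1 -1.37, Fam192a -1.27 and Abca7 -1.23.

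An absolute log2 fold change of at least 0.5 left 786 lower and 19 higher peaks, and a share of at least 5% in both genotypes left 213 lower and 596 higher. Since all the peaks exceed that share in the wild type, the last filter selects on the knockout share itself, and its balance follows from the filter. Peaks outside genes by the RefSeq table made up 34.7% of the lower and 9.54% of the higher peaks. The number of lists standing apart went from 2 to 1 with 1 peak per gene and to 1 with width matched; the chromatin list was lost both times. Lower peaks that overlapped CA1 marker peaks made up 4.37%. They made up 2.4% with strict markers that also had an adjusted p-value under 0.05, and 68.8% with the numbered clusters. Higher peaks that overlapped peaks low in CA1 made up 20.5%, but 0% with the same strict markers and 12.5% with the numbered clusters. Stricter sets hold fewer peaks by construction. Numbered cluster 9 of the CA1 pair had shares near the wild-type CA1 shares, a median of 1.9 percentage points away. Its marker peaks are thus not independent of the genotype comparison, which bears on the overlap of 68.8%. The cause of the other changes was not tested. With width matched, all 5 regions and 15 of 21 chromosomes kept their side of the percentile bounds.

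An adjusted p-value under 0.05 and a share of at least 5% in either genotype removed no listed peak. The share filter could remove none, because each listed peak had at least 10% of nuclei of 1 genotype. Merging peaks within 10 kb and autosomes alone kept both counts within 1.5 times, and with strict markers 18 of 19 numbered clusters had the same closest merged cluster. Promoter windows of either size, motifs, GC content, the central part of peaks and peaks far from start sites were not run. No paired analysis was possible because each genotype has 1 library. Unknown depth limits each share, above all the small knockout shares.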

Other observations

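All the tests of explanations below, and the windows around Htr6, were chosen after the values had been seen.

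The cluster named interneuron_2 had fixed markers of several classes. Of the fixed markers, Reln and Ebf3 of the Cajal-Retzius list were listed as higher (2 of 6), and only Gad1 of the 16 GABAergic markers. Prox1 of the granule cell list had the largest positive log2 fold change of these markers (0.62). It had signal in 68.8% of the cluster's nuclei against 29.5% of other nuclei in the authors' deposited table. Grik4 of the CA3 list and Ntng2 of the subicular list were higher too. Neurod1 and Tbr1, transcription factors of excitatory neurons, had signal in 38.4% and 42% of its nuclei against 9.3% and 16% of other nuclei, and Reln in 70.5% against 43.3%, in the authors' deposited table. Its leading genes by fold change were Ttc28, Macrod1 and Hydin.

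The shares of the merged CA1 cluster were reproduced from the genotypes' shares with a weight of 29.5% for wild type and 70.5% for knockout over 445 peaks, with a largest residual of 0.0891 percentage points. Numbered cluster 1 differed from the knockout CA1 shares by a median of 0.3 percentage points over 53 peaks, and from the wild-type shares by 11.1. Numbered cluster 9 differed from the wild-type shares by 1.9 over 2553 peaks, and from the knockout shares by 12.3. The dentate pair lay near the same CA1 shares: cluster 0 differed by 1.9 from the knockout and 9.8 from the wild-type shares over 99 peaks, and cluster 2 by 2.9 from the wild-type shares over 686 peaks. Other smaller-share members differed. Clusters 7 (CA3), 5 (excitatory_1) and 4 (oligodendrocytes) lay 3, 5.2 and 7.2 from the knockout and 11.1, 12.6 and 10.7 from the wild-type shares. Cluster 8 (astrocytes) was even, at 7.6 and 7.7. Cluster 14 (microglia) lay nearer the wild-type shares, at 4.7 against 10.8. The larger-share members all lay nearer the wild-type shares. For clusters of other cell types these distances are to CA1 shares, so cell type and genotype cannot be told apart in them. Erdr1 gene activity was listed as higher in numbered clusters 15 (44.4% against 14.5% of other nuclei) and 17 (43.8% against 14.8%) in the authors' deposited table, both the larger-share members of their pairs. Around Htr6, 8 of 12 listed CA1 peaks within 2 Mb of the gene were on the higher list, 13 of 29 within 5 Mb and 23 of 48 within 10 Mb, against 21.1% of chromosome 4 peaks; among random chromosome 4 peaks of the same width these lay at percentiles 97.8, 90.9 and 98.5.

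The first pattern is that each of the 4449 CA1 peaks was open in a smaller share of knockout nuclei. Each peak had at least 10% of nuclei of either genotype. All reached that share in the wild type, and only 81 also reached it in the knockout. A threshold on either genotype would also admit peaks that reached it in the knockout alone, but no listed peak was of that kind. Such a threshold therefore does not by itself make the knockout share the smaller one. The authors' filter is not stated. Fewer fragments per knockout nucleus stays open. Of the 4449 peaks, 25% had a positive log2 fold change in spite of the smaller share. The scale of that fold change is not stated, and a centred scale gives both signs by itself. A loss of open chromatin limited to CA1 neurons stays open too. In 6 of the 6 other pairs of numbered clusters, 1 member also had under 0.5 of the other's share, but the tables give no genotype for the numbered clusters of other cell types. A genotype effect on overall accessibility stays open, since library and genotype are confounded.

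The second pattern is that higher peaks were wider and more often exonic. Within 5 groups of like wild-type share, the Spearman correlation across peaks between width and the ratio of rates was at least 0.418. Saturation alone predicts about 0, so saturation of the share is argued against. Peaks are not independent replicates. A first form of this test was replaced because it compared sets split on the outcome. A difference between the libraries in signal over background stays open: within strata of region and share the median correlation of width and log2 fold change was 0.307, but that restates the pattern, any cause linked to width would give it, and the tables hold no measure of signal over background per library. Nuclei or free DNA of other cell types stay open. Marker peaks of 3 of 9 other clusters tested (oligodendrocytes, microglia and astrocytes) were listed higher more often than matched random peaks. With strict markers, the first form of this test, it was 0 of 9. No strict percentile was made for interneuron_1, whose full marker set lay at percentile 58.3. A genotype effect was not tested apart from these explanations.

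The third pattern is Erdr1, whose peaks had ratios of knockout to wild-type share of 0.0129 and 0.055, against a median of 0.213 and a minimum of 0.0769 over the other 4447 peaks. Lower coverage alone is argued against for the peak with the lowest ratio, which lay 9.36 SDs of the log2 ratio below the median of 1190 other peaks of like wild-type share, while those others lay at most 2.43 SDs below. For the other peak it stays open: its distance of 4.72 SDs, where 478 others lay at most 1.67 below, passed a bound of 4.24 that allows for the number of peaks under a normal spread but not a bound of 6 that was also considered, and this was the third test made of that explanation, after 1 that the pattern itself fixed and 1 that was undecided. A missing stretch that spans all the listed chromosome Y peaks is argued against by the third such peak, near Gm21860, whose ratio of 0.241 lay at percentile 70.7 of the peaks outside Erdr1. A smaller sequence or copy-number difference between the animals, unrelated to Htr6, and an effect of the knockout both stay open and were not tested.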
